A study of Rattus norvegicus with 59 samples.

How the data were processed

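RNA of whole kidneys from 59 Fawn-Hooded Hypertensive rats in 12 groups was measured on Illumina RatRef-12 expression arrays, which hold 22523 probes, with 1 array per rat and 10 slides in all. Per the labels' protocols, RNA was isolated with TRIzol and purified with NucleoSpin RNA II, amplified and labelled with the Illumina TotalPrep kit and hybridised by a service provider. Groups came from the sample labels, replicates were numbered within groups in accession order, and slides from the column names of the deposited table. Whether any rats shared a dam is not given in the sources used here. No 2 arrays held the same values.

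The deposited table of intensity values holds 1 mean signal per probe and array, not normalized per its file name, and the column medians differed between arrays. The scanner software and any background treatment are not given in the sources used here. Beside each signal the deposited table gives a detection p-value per the file headers. From its values this p-value was two-sided: it peaked near 1 at 1 signal per array and was small below that signal as well as above it, so that 18.5% to 27.2% of probes on an array (median 21.9%) had a p-value under 0.05 with a signal below background. The value table of the authors holds deposited log2 values. Within each array their ranks equalled those of the signals (rank correlation of 1), they differed by at most 0.0599 from log2 signals after quantile normalization, and their column medians were 6.70 to 6.71. Scale and direction were thus settled, genes were not centred, and the method of normalization is not given in the sources used here. No column of per-sample values was left unused.

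The planned background correction, neqc of limma, takes detection p-values to be one-sided, so it was not valid for these and was adapted. The background level of an array was the median signal of the 50 probes with the highest deposited p-value, and its SD came from the signals below that level, mirrored. Signals were corrected by normexp with these values, 16 was added, arrays were quantile-normalized over all 59 and log2 was taken. A probe was above background on an array at a one-sided normal p under 0.05 against that background, and was tested when above background on at least 4 arrays of its fit. Signals were 67.8 to 202.7 in the median against background levels of 59.9 to 136.6. The number of arrays sets the precision, and a probe near background has little of it.

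Of the probes 13793 had 1 gene symbol, 0 several and 8730 none in the platform annotation. 13752 symbols were matched by gene ID to the gene table of assembly GRCr8, 0 changed, and 13337 genes had a probe. Unnamed probes were tested and counted but not named, and the names of the platform can be old.

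limma 3.58.1 in R 4.3.3 was used (lmFit and eBayes, group means, Benjamini-Hochberg over the probes of a comparison, threshold 0.05). The 18 comparisons were PDTC against untreated in both sexes and each sex at 3 ages, the sex difference of the effect, untreated females against males, 2 weeks against 2 days and adults against 2 weeks in untreated rats, and the age difference of the effect between 2 weeks and 2 days. The arrays of 1 age shared a fit; the comparisons of ages used the untreated groups of both ages, and the last the 8 groups of both. Of 32 gene lists 31 were tested with camera (preset inter-gene correlation 0.01, at least 5 members, 1 probe per gene, Benjamini-Hochberg over lists), again with an estimated correlation, and with fry. The list of sex chromosome genes had 2 of 12 members on the array and was not tested. Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The comparisons, lists and tests were not changed apart from the background step, and exact two-sided permutations of list means, with treatment permuted within sex, were added.

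The rule named, for PDTC in both sexes, the 10 largest rises and falls past the threshold or the 3 smallest p per direction where none passed. For single sexes, sex comparisons and differences of effects it took 5 or the 2 smallest p, and for ages 10. From each list discussed it took the 4 members with the smallest p, and in PDTC comparisons Nfkbia, Ccl2, Icam1, Vcam1, Il1b, Nfkb1, Nfkb2 and Rela. A gene was represented by its probe with the highest mean, and others were named where they disagreed. Names made of LOC or RGD and digits were counted but not named. Where a probe was above background on no array of 1 group, its fold was given as a bound.

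Alternatives were no normexp correction, scaling each array to 1 median in place of quantile normalization, no filter, the deposited log2 values, slide as a fixed term, 1 fit of all 59 arrays, array weights, an estimated correlation for lists and leaving out each array. Added after the data were seen were a filter on the deposited p-value with a signal above background, slide as a random block, leaving out slide 6, slide as a fixed term with an estimated correlation, and that correlation without untreated 2-week male 6. Slides served as batches, since scan dates were not used here. Each comparison was also set against 100 splits of its arrays. In simulated data for PDTC at 2 days (13163 probes, 200 changed by 1.2, 1.5, 2 or 3-fold) limma recovered 10%, 78%, 92% and 98%. There were 8 false calls among 147, while splits of the arrays called up to 500.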

Results

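Kidneys of 59 rats of the Fawn-Hooded Hypertensive strain, which develops high blood pressure and progressive kidney damage, were profiled with 1 expression array each at 3 ages: 2 days, 2 weeks, and adulthood, when males were 36 and females 42 weeks old. Dams drank water with pyrrolidine dithiocarbamate (PDTC), given as an inhibitor of the inflammatory transcription factor NF-kB, at 150 mg per L from 2 weeks before to 4 weeks after birth, or untreated water, so adult rats had last been exposed at 4 weeks of age. The 12 groups were the combinations of age, sex and treatment. At 2 days there were 5 untreated rats and 4 PDTC rats of each sex, at 2 weeks 6 untreated males, 5 untreated females, 4 PDTC males and 6 PDTC females, and in adulthood 5 rats in each of the 4 groups. The litters of the rats are not given in the sources used here, so p-values measure only the spread between these rats, some of which can share a dam. Adult sex was inseparable from age in weeks. The number of arrays limits the precision. On an array 9139 to 12488 of the 22523 probes were above background (medians of 11936 at 2 days, 12121 at 2 weeks and 10188 in adults).

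Age set the kidneys apart most. The component that carried 56.7% of the variance over all arrays ordered them by age (R2 of age 0.973, R2 of slide 0.947). Pups lay on slides 1 to 6, except for untreated 2-week male 6 on slide 8, and adults on slides 7 to 10. That male lay between the ages at 11.5 on this component, against -35.2 to -22.2 for the other 2-week arrays and 56.9 to 92.4 for adults. Arrays of 1 group correlated at 0.947 to 0.997 across probes, and arrays of different groups at up to 0.997. Within each age the first component had an R2 of slide of 0.848 at 2 days, 0.896 at 2 weeks and 0.114 in adults. At 2 weeks untreated male 6 stood apart on it (69.7, others -18.3 to 12.5) and, alone on its slide at that age, was fitted exactly. Component 2 there had 0.962.

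**Figure D1:**
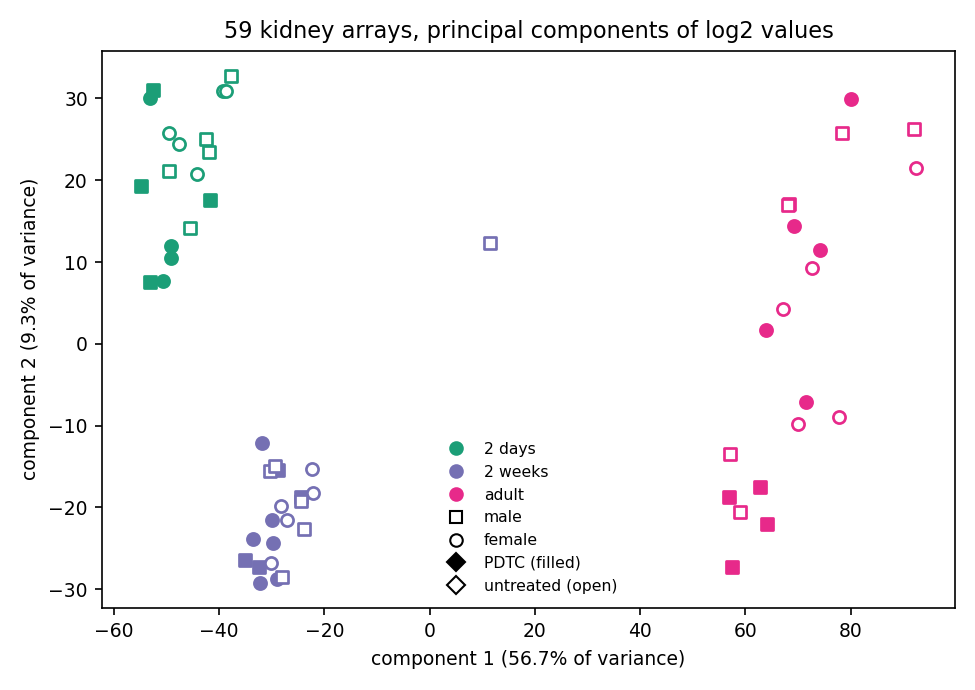
Principal components of the log2 values of all tested probes, with component 1 (56.7% of the variance) on the horizontal and component 2 (9.31%) on the vertical axis. Each point is 1 array, coloured by age, square for males and round for females, filled for PDTC and open for untreated, and along component 1 the 2-day arrays lie at -54.8 to -37.8, the 2-week arrays other than untreated male 6 (11.5) at -35.2 to -22.2 and adults at 56.9 to 92.4.

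The first question was how kidneys of newborns whose dams had been given PDTC, meant to inhibit NF-kB, differed from those of untreated newborns. At 2 days, 23 of the 27 measured genes of extracellular matrix and fibrosis had a higher mean in the 8 PDTC pups than in the 10 untreated pups, with a median log2 difference of 0.17 (camera adjusted p = 7.3e-10, and adjusted p = 0.308 with an estimated correlation). Col1a2 and Col1a1, the chains of collagen I, differed by 0.58 ± 0.11 and 0.41 ± 0.10 (log2 ± SE). Col5a1 and Col5a2, the chains of fibrillar collagen V, differed by 0.35 ± 0.078 and 0.37 ± 0.091, each in 7 or 8 of the 8 PDTC pups. Of the 27 matrix genes, 0 passed over all probes and 12, all higher, passed when adjusted over the list alone. Genes of podocytes, the cells of the glomerular filter, lay the same way in 13 of 16 cases, with a median of 0.12 (camera adjusted p = 0.00131, and adjusted p = 0.270 with an estimated correlation). They included Nphs1, which encodes nephrin of the slit diaphragm, at 0.27 ± 0.068 in 8 of 8 pups and Clic5 at 0.29 ± 0.093 in 6 of 8. Over all probes 0 podocyte genes passed, and 2 did adjusted over the list alone.

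Lower in PDTC pups were 15 of 17 genes of cholesterol synthesis and uptake, with a median of -0.19 (0.0019 with arrays scaled to 1 median, which put the median of all probes at 0.12, so -0.12 relative to all probes; camera adjusted p = 6.5e-04, and adjusted p = 0.601 with an estimated correlation). Idi1, Sqle, Fdps and Msmo1, enzymes of the pathway, lay at -0.33 ± 0.080, -0.33 ± 0.082, -0.27 ± 0.071 and -0.29 ± 0.078, each in 8 of 8 PDTC pups. In this list 4 members lower and 1 higher passed adjusted over the list alone, against 0 over all probes. The respiratory chain lay 39 of 44 genes lower, by a median of -0.079 (0.011 with arrays scaled to 1 median, -0.11 relative to all probes; camera adjusted p = 2.3e-04, and adjusted p = 0.725 with an estimated correlation). Among them Ndufs8, Ndufs7 and Ndufb2 of complex I lay at -0.22, -0.17 and -0.23, with 0 past the test over all probes and 0 adjusted over the list alone. Of the proximal tubule genes, 23 of 26 were lower by a median of -0.16 (camera adjusted p = 0.0239, and adjusted p = 0.868 with an estimated correlation). Dpep1, a brush border dipeptidase, lay at -0.60 ± 0.16 in 7 of 8 pups, while the bicarbonate cotransporter Slc4a4 lay the other way at 0.88 ± 0.35 in 7 of 8. Of these, 0 passed over all probes and 1 adjusted over the list alone. The mean of this list was lower in 4 of 8 PDTC pups (3 of 4 males and 1 of 4 females), that of the respiratory chain in 6 and that of cholesterol genes in 8, while the matrix mean was higher in 8 and the podocyte mean in 7. Outside these groups, Plxna2, a semaphorin receptor, lay at 0.57 ± 0.11 and Col8a1 at 0.97 ± 0.20, and Dnase1, a secreted nuclease, at -0.92 ± 0.19, Cyp4b1 at -0.46 ± 0.097 and Serhl2 at -0.37 ± 0.075, each in 8 of 8 PDTC pups. Untreated pups were above background in 8 of 10 cases for Plxna2 and in 5 of 10 for Col8a1.

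None of these genes passed the test over all probes. Over all probes limma called 0 of 13163 probes, with a smallest adjusted p of 0.125, while 2085 had an unadjusted p under 0.05, against 658 expected with no difference. Without slide 6, which held 3 untreated but no PDTC pups of that age, this number was 923, in fewer arrays. The camera test, which sets a list against all other genes, called these 5 of 31 lists with a preset inter-gene correlation and 0 with an estimated one. The fry test, whose p tests if the genes of a set move on balance one way, gave adjusted p = 0.0345 for matrix, 0.0286 for podocytes and 0.0400 for cholesterol, and 0.122 and 0.476 for the other two. In an exact two-sided permutation of treatment within each sex, added after camera's calls were seen, the list means gave p = 0.00252 (adjusted over 31 lists, 0.0325) for matrix, 9.4e-04 (0.0293) for podocytes and 0.00315 (0.0325) for cholesterol. They gave 0.0254 (0.193) for the respiratory chain and 0.264 (0.501) for proximal tubule. With slide as a block the matrix median was 0.13 (adjusted p = 0.0885 with an estimated correlation) and the podocyte median 0.14 (0.0885). Within slides both lists were higher on 5 of 5 slides, the respiratory chain lower on 5, cholesterol on 4 and proximal tubule on 3. Single arrays moved the probe count from 0 to 258 (195 higher, 63 lower) without untreated male 4, to 34 (18 higher, 16 lower) without PDTC male 4 and to 1 without untreated female 3, and array weights moved it to 373 (261 of them higher).

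**Figure D2:**
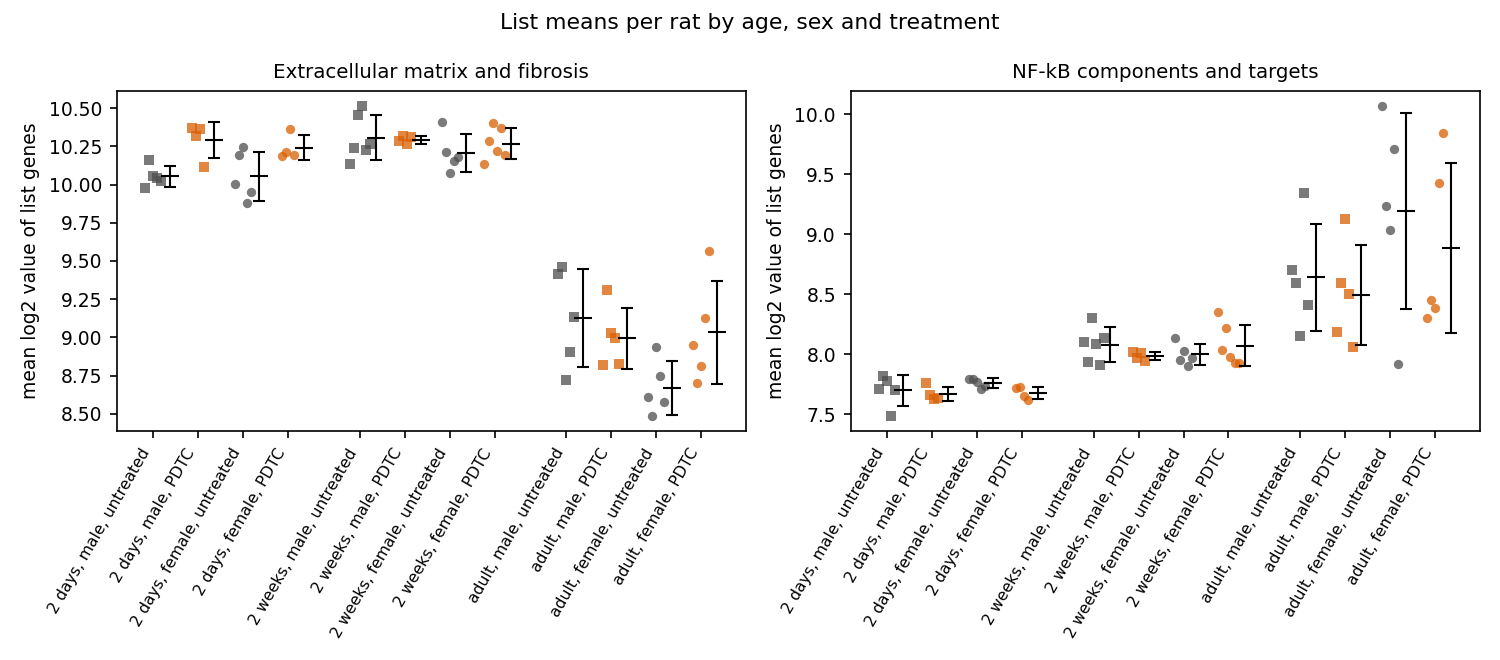
Mean log2 value of the matrix list and of the NF-kB list in each rat (points; grey untreated, orange PDTC), by age and sex, with bars for the group mean ± SD. At 2 days the matrix list stood at 10.29 ± 0.12 (n = 4) in PDTC males against 10.05 ± 0.069 (n = 5) in untreated males and at 10.24 ± 0.084 (n = 4) against 10.05 ± 0.16 (n = 5) in females, and the NF-kB list at 7.67 ± 0.062 against 7.70 ± 0.13 and at 7.68 ± 0.053 against 7.76 ± 0.039.

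Taken by sex, matrix and podocyte genes were higher and cholesterol genes lower in PDTC pups of both sexes at 2 days. The matrix median was 0.26 in males and 0.15 in females, the podocyte median 0.15 and 0.13, and the cholesterol median -0.20 and -0.11 (in females 0.12 with arrays scaled to 1 median, which put the median of all probes at 0.14, so -0.027 relative to them). With an estimated correlation these lists had adjusted p = 0.347 to 0.766 in males and 0.613 in females. In males, proximal tubule genes had a median of -0.37, with the glucose transporter Slc5a2 at -1.37 ± 0.57 in 3 of 4, and the respiratory chain one of -0.12. In females the proximal tubule median was -0.048 (0.13 with arrays scaled to 1 median, -0.0086 relative to all probes), the mean of its genes lay the other way at 0.013, and the list was not called (camera adjusted p = 0.937). The kinase Sgk1, a mediator of aldosterone action, lay at -0.90 ± 0.15 in 4 of 4 males (limma adjusted p = 0.243). Hmox1, heme oxygenase, lay at -0.82 ± 0.33. In females, leukocyte genes had a median of -0.10 (0.030 with arrays scaled to 1 median, -0.11 relative to all probes). S100a8, a granulocyte protein, lay at -0.72 ± 0.15 in 4 of 4 females (limma adjusted p = 0.631). In all, limma called 0 probes in either sex (1476 with an unadjusted p under 0.05 in males, 968 in females; without slide 6, 1080 and 550). In turn, camera called 5 lists in males and 4 in females with the preset correlation, those named here, and 0 with an estimated one. The difference between the sexes, tested itself, gave 0 probes (309 with an unadjusted p under 0.05, 676 without slide 6) and 3 lists: proximal tubule at 0.40, the respiratory chain at 0.081 and metal response at 0.17 (female minus male effect), with adjusted p = 0.622, 0.634 and 0.622 with an estimated correlation. Without PDTC male 4 the count of probes in males was 4, and with slide as a random block it was 1.

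At 2 weeks, with exposure still going on, the comparison of 10 PDTC and 11 untreated rats asked which differences the growing kidney carried. Among leukocyte genes 18 of 23 were lower in PDTC rats by a median of -0.096 (camera adjusted p = 0.0174, and adjusted p = 0.448 with an estimated correlation). The T cell chemokine Ccl5 lay at -0.54 ± 0.19 in 9 of 10 rats and Cd74 and Cd79b of antigen-presenting and B cells at -0.28 ± 0.12 and -0.28 ± 0.10, each in 9 of 10. Among immediate early genes, which respond within minutes to stimulation, 16 of 23 were lower by a median of -0.11 (0.045 with arrays scaled to 1 median, which put the median of all probes at 0.13, so -0.088 relative to all probes; camera adjusted p = 0.0174, and adjusted p = 0.691 with an estimated correlation). Ier2 lay at -0.30 ± 0.10, Jun at -0.30 ± 0.12, Zfp36 at -0.25 ± 0.10 and Dusp1 at -0.24 ± 0.10, in 9, 7, 8 and 9 of 10 rats. The respiratory chain had 36 of 44 genes lower at a median of -0.056 (0.021 with arrays scaled to 1 median, -0.11 relative to all probes; camera adjusted p = 0.00225, and adjusted p = 0.691 with an estimated correlation). Podocyte genes were higher in 16 of 18 cases (median 0.11; camera adjusted p = 0.0307, and adjusted p = 0.707 with an estimated correlation). The transcription factor Wt1 lay at 0.38 ± 0.15 and the phosphatase Ptpro at 0.23 ± 0.11 in 10 of 10 rats each. Cell cycle genes were higher in 27 of 33 (median 0.081; camera adjusted p = 0.0229, and adjusted p = 0.887 with an estimated correlation). The single genes with the smallest p were Lnx2 at 0.56 ± 0.13, above background on 2 of 11 untreated arrays, Atxn3 at 0.37 ± 0.095, Errfi1, a feedback inhibitor of EGF receptor signalling, at -0.41 ± 0.10, Ubd at -0.43 ± 0.11 and Abhd1 at -0.28 ± 0.075, in 9 or 10 of 10 rats.

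Of these genes 0 passed over all probes and 0 adjusted over the list alone. In this comparison limma called 0 of 13360 probes (smallest adjusted p = 0.825; 697 with an unadjusted p under 0.05). The camera test called these 5 lists with the preset correlation and 0 with an estimated one. The exact permutation of list means gave a smallest adjusted p of 0.471 over 31 lists. The leukocyte mean was lower in 9 of 10 PDTC rats, the immediate early mean in 7 and the respiratory chain mean in 10, and the podocyte and cell cycle means were higher in 9 and 8. Within slides leukocyte genes were lower on 4 of 6, immediate early genes on 6 and the respiratory chain on 5, and cell cycle and podocyte genes were higher on 5 and 4. The count of called lists went to 8 without untreated female 1, to 2 without PDTC male 1, and to 3 without untreated female 3 or without PDTC female 3. Untreated male 6, between the ages in the components, had the highest Cd74 of its group (log2 10.1) and the lowest Ptpro (10.3) and Wt1 (6.20). Without it limma again called 0 probes (712 with an unadjusted p under 0.05). The podocyte median was then 0.052 and no longer called (camera adjusted p = 0.0942). The immediate early median was -0.052 and the leukocyte median -0.11, both still called with the preset correlation. Fatty acid oxidation genes at -0.045 (adjusted p = 0.0355) were called as well, and none of these held with an estimated correlation (adjusted p = 0.295 to 0.918).

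By sex at 2 weeks, PDTC males had leukocyte genes at a median of -0.18, with Ccl5 at -0.86 ± 0.27, erythroid genes at -0.25 (0.020 with arrays scaled to 1 median, which put the median of all probes at 0.21, so -0.19 relative to them) and cell cycle genes at 0.14. Without untreated male 6 the male medians were -0.13, -0.15 and 0.075, interferon genes at -0.096 were called as well (camera adjusted p = 0.00598, and adjusted p = 0.557 with an estimated correlation), and leukocyte genes were called with an estimated correlation too (adjusted p = 0.0491). In PDTC females immediate early genes lay at -0.12, the respiratory chain at -0.055, arachidonic acid metabolism at -0.078, proximal tubule at -0.075 and tubular injury and repair at 0.099. Without untreated male 6, which enters the shared spread, podocyte genes at 0.12 and fatty acid oxidation genes at -0.075 were called in females as well (adjusted p = 0.684 each with an estimated correlation). With all arrays, camera called the other lists named here with the preset correlation, and none held with an estimated one (adjusted p = 0.145 to 0.690 in males and 0.689 to 0.694 in females). Kap, an androgen-responsive kidney protein, lay at -0.86 ± 0.20 in 6 of 6 PDTC females (limma adjusted p = 0.999). The limma fit called 0 probes in each sex (432 in males and 422 in females with an unadjusted p under 0.05). Between the sexes 0 probes differed (186 with an unadjusted p under 0.05, and 100 to 389 with 1 array left out). Here camera called 5 lists, with adjusted p = 0.431 to 0.656 with an estimated correlation. Erythroid genes lay at 0.19 and tubular injury at 0.14 (-0.071 with arrays scaled to 1 median, which put the median of all probes at -0.14, so 0.070 relative to them). Leukocytes lay at 0.12, NF-kB components and targets at 0.11 (-0.0042 and 0.14 likewise) and proximal tubule at -0.17.

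The PDTC effect at 2 weeks was set against that at 2 days in 1 test. Matrix genes differed by -0.18 (median log2, effect at 2 weeks minus effect at 2 days), adipose genes by -0.26 and immediate early genes by -0.085. Cholesterol genes at 0.15, proximal tubule genes at 0.14 and cell cycle genes at 0.095 lay the other way. In turn, camera called these 6 lists with the preset correlation (adjusted p = 4.5e-08 for matrix) and 0 with an estimated one (adjusted p = 0.347 to 0.930). Over all probes limma called 0 of 14079 probes, with 473 at an unadjusted p under 0.05, and 1 without PDTC male 4 of 2 weeks.

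In adults, long after exposure had ended at 4 weeks, 10 rats exposed to PDTC early in life were compared with 10 untreated rats, to ask which differences lasted. Proximal tubule genes were lower in 20 of 26 cases, with a median of -0.22 (camera adjusted p = 0.00380, and adjusted p = 0.753 with an estimated correlation). Slc22a8 and Slc22a6, the organic anion transporters OAT3 and OAT1, lay at -0.47 ± 0.16 and -0.25 ± 0.10, Slc13a3, a dicarboxylate transporter, at -0.32 ± 0.11 and Slc26a1, a sulfate transporter, at -0.35 ± 0.17, in 10, 9, 10 and 8 of 10 rats. The nucleoside transporter Slc28a1, above background on 6 of 10 PDTC and 9 of 10 untreated arrays, lay at -0.78 ± 0.22, and Ephx1, an epoxide hydrolase, at -0.40 ± 0.12 in 10 of 10. Higher were Clec7a, the beta-glucan receptor of myeloid cells, at 1.14 ± 0.30, and Cblb, a ubiquitin ligase that restrains lymphocyte activation, at 0.81 ± 0.23, each in 10 of 10 rats and above background on 7 and 9 of 10 untreated arrays. Pcgf2, a Polycomb protein, lay at -0.37 ± 0.087. In all, limma called 0 of 11701 probes (smallest adjusted p = 0.799; 668 with an unadjusted p under 0.05). The proximal tubule list was camera's only call, with 0 members past the test over all probes and 0 adjusted over the list alone. Its mean was lower in 7 of 10 PDTC rats, 5 of 5 females (median -0.29) and 2 of 5 males (median -0.096, camera adjusted p = 0.254). Its exact permutation p was 0.193 (adjusted 0.769), and the list was lower on 4 of 4 slides, without matching sex. Without single arrays the number of lists called ran from 0 (untreated male 5) to 7 (PDTC male 5 or PDTC female 2). A fit over all 59 arrays called 51 probes (28 higher, 23 lower). It shares 1 spread over ages, while separate fits had a median SE of 0.17 in adults against 0.099 and 0.11 in pups. Its adult counts can thus be too high.

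The adult sexes were then taken apart. In PDTC females, genes of tubular injury and repair had a median of 0.41 (16 of 20 higher), leukocyte genes 0.43, the interferon response 0.36, matrix 0.33, complement and coagulation 0.44 and cell cycle 0.26. Proximal tubule genes lay at -0.29 and organic ion transporters at -0.38 (adjusted p = 0.435 to 0.515 with an estimated correlation for these 8 lists). Among the injury genes, Anxa1, an anti-inflammatory annexin, lay at 0.85 ± 0.21, the hyaluronan receptor Cd44 at 1.22 ± 0.34 (above background on 1 of 5 untreated arrays), Clu, clusterin, at 0.82 ± 0.27 and Vim, vimentin, at 0.86 ± 0.31. Col3a1 of collagen III lay at 1.2 ± 0.40, Fgb, a fibrinogen chain, at 1.16 ± 0.45 and the leukocyte antigen Cd53 at 1.10 ± 0.45, in 5, 5 and 5 of 5 females, and the anion transporter Slc22a13 at -1.46 ± 0.59 in 4 of 5. In PDTC males the leukocyte median was -0.39 and that of cell cycle genes -0.21, the ribosomal protein median -0.090, and circadian clock genes lay at 0.27 (adjusted p = 0.861 to 0.871 with an estimated correlation for these 4 lists). Of the clock genes Nfil3, Per1 and Usp2 lay at 1.13 ± 0.38, 1.0 ± 0.36 and 1.02 ± 0.45, each in 5 of 5 males. Aqp2, the vasopressin-regulated water channel, lay at 0.90 ± 0.21 and Abcc8, a subunit of ATP-sensitive potassium channels, at 1.06 ± 0.23 (above background on 3 of 5 untreated arrays).

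The male medians of injury, interferon, matrix and complement genes were -0.23, -0.16, -0.17 and -0.17, and these lists were not called (camera adjusted p = 0.0712 to 0.522). None of the genes named for 1 adult sex passed the test. The limma fit called 0 probes in adult males (945 with an unadjusted p under 0.05; 38 with array weights, 303 in a fit of all 59 arrays and 10 without PDTC male 2) and 0 in adult females (681; 129 in the fit of all 59 arrays). Of the injury genes 3 passed in females adjusted over the list alone. The camera test called the 8 lists in females (adjusted p = 7.0e-06 for injury, 1.8e-05 for leukocytes) and the 4 in males (adjusted p = 0.00603 for leukocytes), and none of these held with an estimated correlation. The difference between the sexes, female minus male effect, was tested itself. Leukocyte genes differed by a median of 0.77, complement 0.68, injury 0.60, interferon 0.59, matrix 0.50, cell cycle 0.39 and ribosomal proteins 0.18. Organic ion transporters lay at -0.17, heat shock proteins at -0.28 and circadian genes at -0.33. These were camera's 10 calls, and 0 held with an estimated correlation (adjusted p = 0.537 to 0.767). An exact permutation of list means gave p = 0.0433 for leukocytes, 0.0567 for injury and 0.167 for interferon, unadjusted. Single genes of that difference included Anxa1 at 1.14 ± 0.30, Col3a1 at 1.76 ± 0.56 and Cd53 at 1.74 ± 0.63. Anxa1 had a limma adjusted p of 0.630, and 0 probes were called (919 with an unadjusted p under 0.05; 1 with array weights, 435 in the fit of all 59 arrays and 2 without untreated female 4).

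**Figure D3:**
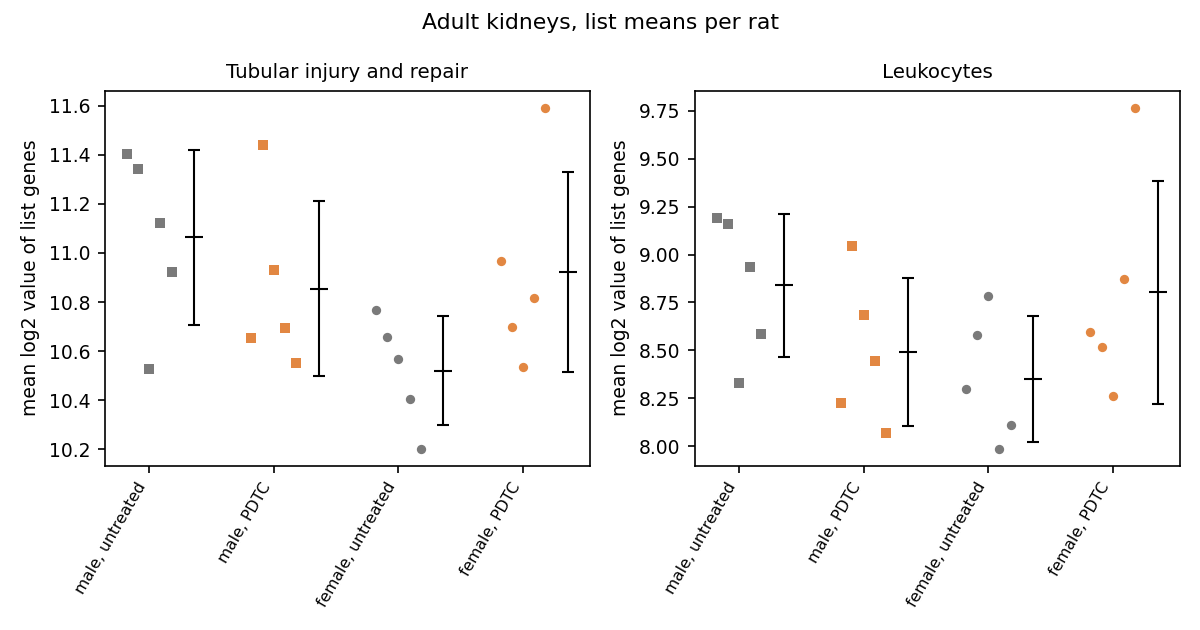
Mean log2 value of the injury and repair list and of the leukocyte list in each adult rat (points; grey untreated, orange PDTC), by sex, with bars for the group mean ± SD (n = 5 each). The injury list stood at 11.06 ± 0.36 in untreated and 10.85 ± 0.36 in PDTC males, and at 10.52 ± 0.22 in untreated and 10.92 ± 0.41 in PDTC females, with ranges that overlap.

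Components and targets of NF-kB, the pathway PDTC was given to inhibit, were not called as a list at any of the 3 ages. Their median difference was -0.080 at 2 days (17 of 27 lower), -0.0092 at 2 weeks (14 of 28 lower) and -0.11 in adults (27 of 31 lower). Arrays scaled to 1 median gave 0.079 and 0.14 at 2 days and 2 weeks (-0.045 and 0.011 relative to all probes). The list gave camera adjusted p = 0.430, 0.816 and 0.0537 and exact permutation p = 0.158, 0.870 and 0.405. Nfkbia, the inhibitor whose own gene NF-kB activates, lay at -0.13 ± 0.063, -0.067 ± 0.090 and 0.38 ± 0.29 at the 3 ages, and Il1b at -0.16 ± 0.066 at 2 days, in 8 of 8 PDTC pups. Vcam1, a leukocyte adhesion molecule, lay at 0.33 ± 0.089 at 2 days in 7 of 8 pups (limma adjusted p = 0.138), at 0.033 ± 0.081 at 2 weeks and at -0.68 ± 0.31 in adults. The monocyte chemokine Ccl2 lay at -0.026 ± 0.12, 0.30 ± 0.29 and -0.81 ± 0.54. Icam1 at -0.13, Nfkb1 at -0.19, Nfkb2 at -0.063 and Rela at -0.080 had limma adjusted p of 0.574 or more at 2 days, and over the 8 genes and 3 ages 0 passed. PDTC binds metals and is an antioxidant. The Nrf2 antioxidant list had medians of -0.082 at 2 days (0.10 with arrays scaled to 1 median, -0.021 relative to all probes), 0.022 at 2 weeks and -0.11 in adults. Metal response and handling had -0.081 (0.021 and -0.10 likewise), -0.0022 (0.093 and -0.041) and 0.019. With camera the adjusted p were 0.246, 0.865 and 0.239 for the first list (exact permutation p = 0.0431, adjusted 0.199, at 2 days, when its mean was lower in 8 of 8 PDTC pups) and 0.476, 0.955 and 0.841 for the second. Mt3, a metallothionein, lay at -0.52 ± 0.11 in 8 of 8 PDTC pups at 2 days (limma adjusted p = 0.125). In simulated data, limma recovered 78%, 84% and 44% of probes changed by 1.5-fold at the 3 ages. It recovered 92%, 96% and 86% at 2-fold and 10%, 10% and 0% at 1.2-fold. Other splits of these arrays called up to 500, 1585 and 369 probes, so simulated rates need not apply. The median 95% confidence half-width of a probe was 0.21, 0.22 and 0.36 (log2).

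**Figure D4:**
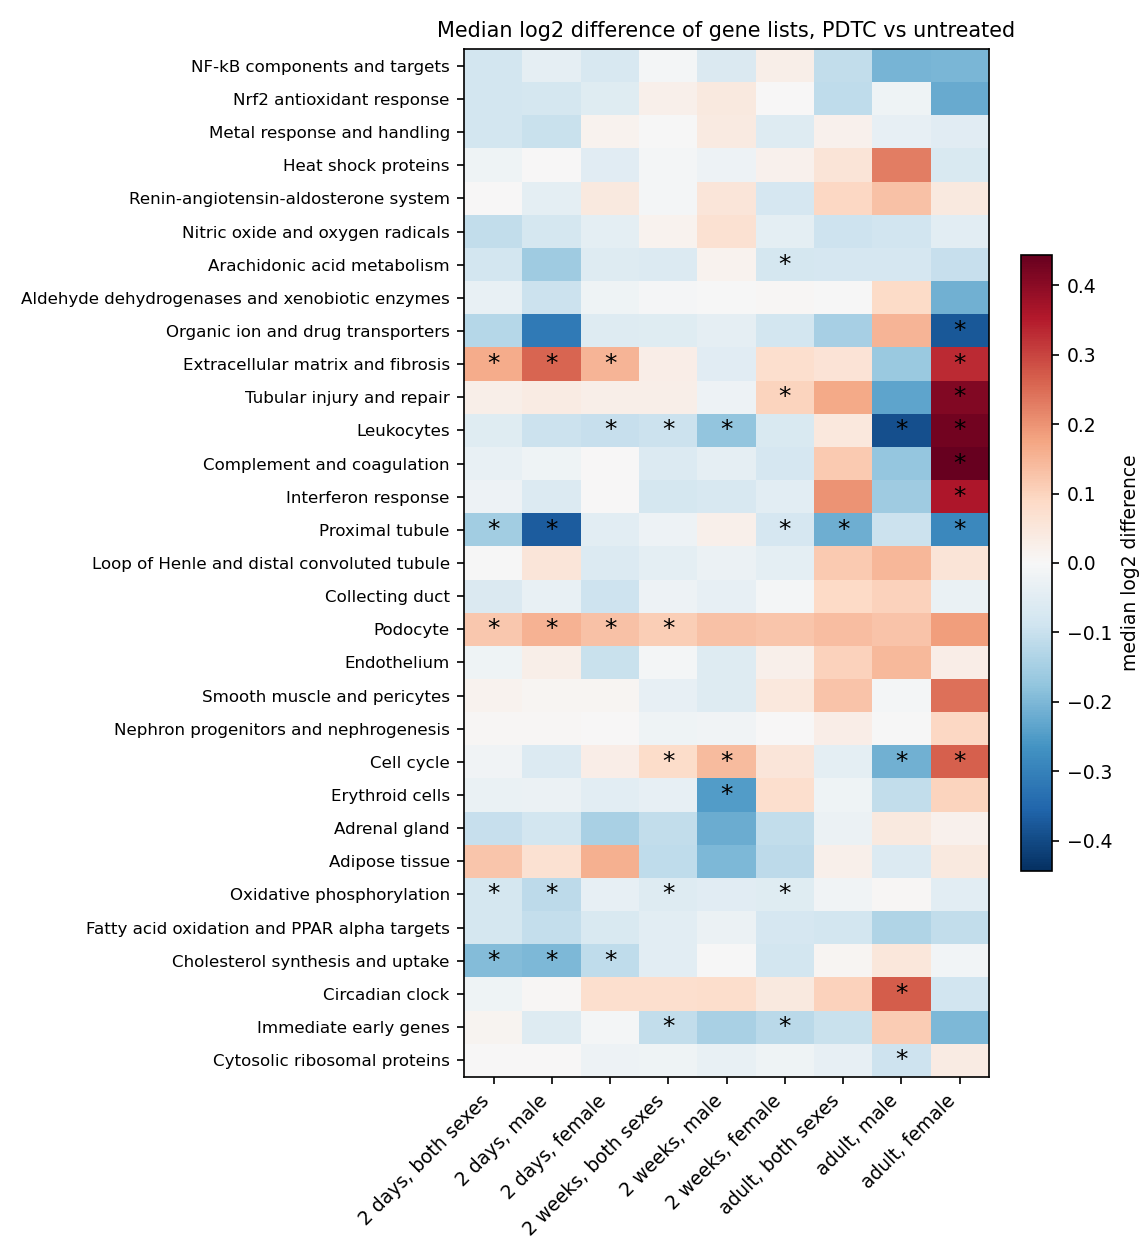
Median log2 difference between PDTC and untreated rats (colour scale) of the 31 gene lists (vertical axis) in the 9 PDTC comparisons of both sexes, males and females at 3 ages (horizontal axis), with an asterisk where camera called the list with the preset correlation; no call held with an estimated one. With arrays scaled to 1 median, called medians turned sign for the respiratory chain at 2 days (0.011) and 2 weeks (0.021), for cholesterol at 2 days (0.0019; 0.12 in females), for leukocytes in 2-day females (0.030), for immediate early genes at 2 weeks (0.045) and for erythroid genes in 2-week males (0.020), and medians near 0 of lists not called turned as well.

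Untreated females were compared with untreated males at each age. Adult females had Adh6, an alcohol dehydrogenase, at least 29.6-fold higher (limma adjusted p = 3.1e-08), and the anion transporter Slc22a13 at least 15.5-fold higher (3.7e-05). They had the organic anion transporter Slc22a7 4.65 ± 0.40 (4.1e-07; above background on 4 of 5 male arrays) and Sds, serine dehydratase, 3.81 ± 0.79 (0.0149) higher on the log2 scale. Angpt2, a vessel growth factor, was 3.96 ± 0.52 higher (2.1e-04; above background on 4 of 5 male arrays). Lower in females were Slc22a22, a prostaglandin transporter, by at least 14.4-fold (1.2e-10) and Slc51b, a bile acid transporter subunit, by at least 6.0-fold (4.5e-08). Dhrs7l1 lay at -6.16 ± 0.40 (9.2e-09), Cyp2d5 at -4.00 ± 0.36 (7.6e-07) and Akr1c12l1 at -2.99 ± 0.42 (3.4e-04), with Dhrs7l1 and Cyp2d5 above background on 1 of 5 female arrays each. Each of these 10 genes had its direction in 5 of 5 females. A bound set the mean of the brighter group against the higher of the dimmer probe's own signal and the lowest signal above background on each array.

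Injury, matrix, cell cycle, leukocyte, interferon and complement lists were lower in adult females than in males (camera adjusted p = 7.2e-08 for injury to 0.00155 for complement, and adjusted p = 0.366 to 0.898 with an estimated correlation). Of 20 injury and repair genes 18 were lower in females, by a median of -0.55: Cd44 lay at -1.81 (limma adjusted p = 0.00579; above background on 1 of 5 female arrays) and Clu at -1.27 (0.0163), and Spp1, osteopontin, at -0.71 (0.0554) did not pass. Over all probes 2 members were called, and 1 higher and 11 lower adjusted over the list alone. The complement gene C4b (-1.43, 0.0176), the mitotic genes Kif11 (-1.03, 0.0254) and Ccnb2 (-1.13, 0.0387) and the prostaglandin D synthase Ptgds (-2.23, 1.2e-04) were lower in females too. A further probe of Kif11 at the same size did not pass. List medians were -0.52 for cell cycle (2 called, 6 adjusted over the list alone), -0.57 for matrix (0 and 12, with 1 higher), -0.53 for interferon, -0.41 for leukocytes and -0.55 for complement (1 and 3). Arachidonic acid metabolism lay at -0.28, with 2 members lower and 1 higher: Cyp4a2, which makes the vasoconstrictor 20-HETE, lay at -1.24 (0.0472), and Cyp4f1 was higher at 1.36 (0.0250; 0.0642 with slide as a block). Higher in females were adipose genes (0.27) and NF-kB components and targets (0.43, 23 of 31), with adjusted p = 0.432 and 0.898 with an estimated correlation.

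Over all probes limma called 157 of 11701 probes between adult sexes, 87 higher and 70 lower in females, and 1241 had an unadjusted p under 0.05. Of the called probes 60 genes were named higher, 52 lower, and 44 probes had no usable name. In turn, camera called the 9 lists. None held with an estimated correlation (adjusted p = 0.112 for arachidonic acid metabolism, for which fry gave 2.2e-04, and 0.366 to 0.898 for the other 8). The count of called probes was 88 to 171 with 1 array left out, 42 with arrays scaled to 1 median, 237 with array weights and 1018 in the fit of all 59 arrays. Leaving out single untreated arrays ended the call of Sds without female 1 or 4 (3.35 to 3.44), Clu without male 1 or 2 or female 1 or 4 (-1.2 to -1.08), C4b without male 1, 2 or 5 or female 5 (-1.39 to -1.34), Kif11 without male 1, 2, 4 or 5 or female 1, 3 or 4 (-1.07 to -0.94), Ccnb2 without male 1, 2 or 5 or female 1, 2 or 4 (-1.12 to -0.98), Cyp4f1 without male 1, 2 or 5 or female 1, 4 or 5 (1.19 to 1.37) and Cyp4a2 without male 1, 2, 3 or 5 or female 1, 2, 3 or 4 (-1.36 to -1.06).

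In pups the sexes lay close. At 2 days limma called 0 probes between untreated sexes (224 with an unadjusted p under 0.05), and the clock gene Per1 had the smallest adjusted p, 0.169, at -0.92 ± 0.15 in 5 of 5 females. Per1 was the 1 probe called with no background correction, the deposited values, array weights, a random block for slide and without untreated female 2. Its adjusted p ran from 0.0138 to 1.0 over all alternatives. Without slide 6 Per1 lay at -0.69 (adjusted p = 0.999), and 1 other probe, higher in females, was called. At 2 weeks limma called 0 probes (368 with an unadjusted p under 0.05). The camera test called 0 lists at 2 days and 5 at 2 weeks. Adipose genes at -0.32 and cell cycle genes at 0.14 were among these (adjusted p = 0.679 with an estimated correlation for all 5). Matrix lay at -0.12 (0.048 with arrays scaled to 1 median, -0.051 relative to all probes), injury at -0.089 (0.082, -0.018) and ribosomal proteins at -0.030 (0.079, -0.021). Without untreated male 6 the adipose and cell cycle medians were -0.28 and 0.068, and ribosomal proteins were no longer called (camera adjusted p = 0.0699), while proximal tubule genes at 0.084 were called as well (adjusted p = 0.0200, and adjusted p = 0.684 with an estimated correlation). The sex labels were not checked with fixed markers. Only 2 of 12 genes of the sex chromosome list had a probe, fewer than the 5 that a list test needed.

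Untreated rats were compared at 2 days and 2 weeks. Egf, a growth factor made in the distal tubule, rose 26.4-fold (4.72 ± 0.18 on the log2 scale, limma adjusted p = 1.0e-14), Kap by 3.82 ± 0.15 and the folate hydrolase Folh1 by 3.39 ± 0.15. The lipoxygenase Alox15 rose by 3.34 ± 0.17, the sulfotransferase Sult1c2 by 3.41 ± 0.12 and Dio1, the enzyme that activates thyroid hormone, by 3.29 ± 0.096. Hnmt, which degrades histamine, rose at least 9.96-fold and Thrsp, a lipogenic gene, at least 8.90-fold. Ucp1, the uncoupling protein of brown fat, rose by 5.95 ± 0.58 (4.4e-08). Attached fat was not tested, so Ucp1 and adipose genes may not be from kidney. Cyp24a1, the vitamin D 24-hydroxylase, fell by 5.24 ± 0.33 (6.0e-11), the fetal growth factor Igf2 by 2.66, Etv4, a transcription factor of the ureteric bud, by 3.18 and Spock2 by 2.85. Also lower were Shisa3 by 2.72, Afp, alpha-fetoprotein, by 2.63 ± 0.36 and S100a8 by 2.61, while C1qtnf12 was at least 9.13-fold lower. Above background were Ucp1 and Folh1 on 2 of 10 2-day arrays and Etv4 on 1 of 11 2-week arrays. Each named gene had its direction in 11 of 11 2-week rats.

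From 2 days to 2 weeks, of 33 cell cycle genes 31 fell and 2 did not pass (median -0.68), with Mcm3 of DNA replication at -1.28 and Hmgb2 at -1.22. Of 49 ribosomal protein genes 43 fell (median -0.38), Rps2 by 0.91 and Rpl31 by 1.19. Of 21 genes of nephron progenitors 12 fell and 1 rose (median -0.56), the ureteric bud gene Wnt11 by 2.23 (above background on 8 of 11 2-week arrays) and the GDNF receptor Gfra1 by 1.46. Rising were 12 of 14 organic ion transporters (median 0.79; Slc22a7 2.81, Slc22a2 1.57), 16 of 25 collecting duct genes (median 0.64; Car15 3.23, Hsd11b2 1.51) and 12 of 18 genes of the loop of Henle and distal tubule (median 0.56; Umod, uromodulin, 1.92). In these lists 1, 4 and 1 members fell. Rising too were 11 of 15 genes of the renin-angiotensin-aldosterone system (median 0.45; Agtr1a 0.74) and 10 of 24 of nitric oxide and oxygen radicals (median 0.26; Nox4 2.04). Agtr2, the angiotensin receptor of fetal tissue, fell by 2.35, to above background on 2 of 11 arrays. Also rising were 11 of 24 of arachidonic acid metabolism (median 0.29; Cyp2j3 1.63) and 18 of 27 NF-kB components and targets (median 0.38; Ptgs2 1.48, Cx3cl1 1.07). Of these lists 1, 2, 2 and 1 members fell.

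These 10 lists held with an estimated correlation (camera adjusted p = 0.00403 to 0.0382), and with slide as a block as well the smallest was 0.0514. Adjusted over the list alone the counts were 31 lower for cell cycle, 44 for ribosomal proteins and 13 for nephron progenitors, and 12, 16, 12, 11, 10, 11 and 19 higher for the other 7 in the order given. Further lists were called with the preset correlation alone (adjusted p = 0.0514 to 0.404 with an estimated correlation): 19 of 26 proximal tubule genes rose (median 0.67; the water channel Aqp1 1.08), 14 of 18 adipose genes (median 1.01; Fabp4 2.41) and 9 of 14 erythroid genes (median 0.45; Hbb-b1 0.92). So did 17 of 34 of fatty acid oxidation (median 0.28; Hadh 1.01), 9 of 18 interferon genes (median 0.39), 13 of 44 of the respiratory chain (median 0.10) and 11 of 23 Nrf2 genes (median 0.20; Gclc 1.13). Also rising were 10 of 23 immediate early genes (median 0.24), 7 of 17 endothelial genes (median 0.16) and 9 of 27 matrix genes (median 0.20). Of 17 cholesterol genes 8 fell (median -0.29; Sqle -0.84). Adjusted over the list alone 20, 15, 10, 17, 9, 13, 11, 11, 7 and 9 rose in this order and 8 cholesterol genes fell. In all, limma called 5059 of 13378 probes, 2258 higher and 2801 lower at 2 weeks. The count was 2722 (1384 higher, 1338 lower) with arrays scaled to 1 median.

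The change from 2 weeks to adulthood was taken in the same way, but 10 of 11 untreated 2-week arrays lay on other slides than the 10 adult ones. Age and slide were thus joined by 1 array, untreated male 6, which lay between the ages in the components. Without it 8761 probes were called (4357 higher, 4404 lower), and slide as a block could not be fitted. Adult kidneys had the fatty acid hydroxylase Cyp4a8 at least 46.7-fold higher (limma adjusted p = 1.8e-15), the glucuronosyltransferase Ugt2b35 at least 37.8-fold, Sds at least 19.2-fold, and Cyp24a1, which had fallen by 2 weeks, higher by 4.80 ± 0.31. Serpinc1, antithrombin, rose by 4.72 ± 0.14, Resp18 by 4.62 ± 0.15, Akr1c12l1 by 4.50 ± 0.21, Fcgr3a, an Fc receptor of myeloid cells, by 4.31 ± 0.24 and Pzp by 4.04 ± 0.23. Lower in adults were Alox15 by at least 55.0-fold (1.6e-22), Ucp1 by at least 45-fold and the urea transporter Slc14a2 by at least 35.2-fold (a further probe lay at -1.2). So were elastin, Eln, by at least 15.5-fold, Afp by at least 13.4-fold and the neurofilament Nefl by at least 8.56-fold. Col1a1 fell by 4.90 ± 0.27 and Lgals5 by 4.46. Of the 11 2-week arrays, Serpinc1 was above background on 3, Akr1c12l1 and Fcgr3a on 6 and Pzp on 4, and of the 10 adult arrays Col1a1 on 4 and Lgals5 on 3. With slide as a block Apcs (4.56), Sv2b (-4.85), Ptgs2 (-4.65) and Junb (2.40) no longer passed, at 3.08, -3.21, -2.60 and 1.99 (limma adjusted p = 0.0759, 0.149, 0.10 and 0.122). Each named gene had its direction in 10 of 10 adults.

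From 2 weeks to adulthood 31 of 33 cell cycle genes fell (median -2.34; cyclin A2, Ccna2, by at least 8.74-fold), the only list that held with an estimated correlation (camera adjusted p = 0.0153; 0.0899 with slide as a block as well). The 13 lists that follow were called with the preset correlation alone (adjusted p = 0.116 to 0.345 with an estimated correlation). Falling were 20 of 27 for matrix (median -1.46; Postn -3.94, above background on 1 of 10 adult arrays, and Fn1 -3.29), 10 of 14 for smooth muscle and pericytes (-1.12) and 12 of 16 for endothelium (-0.77, although Vwf rose by 2.57). So did 9 of 14 for erythroid cells (-0.72), 11 of 17 for podocytes (-0.65) and 30 of 49 for ribosomal proteins (-0.37). Rising were 20 of 24 leukocyte genes (median 1.67; Cd74 3.14, Cd3g 2.72, above background on 8 of 11 2-week arrays) and 13 of 20 of complement and coagulation (1.29; C4b 3.03). Likewise rising were 14 of 20 interferon genes (0.58; Psmb8 2.78), 23 of 31 NF-kB components and targets (1.21; Ccl20 3.21) and 13 of 23 immediate early genes (0.68; Junb 2.40; -0.12 with arrays scaled to 1 median, 0.45 relative to all probes). So did 17 of 26 proximal tubule genes (0.48; -0.14, 0.44) and 20 of 44 of the respiratory chain (0.18; -0.39, 0.18). Adjusted over the list alone 20 matrix, 10 smooth muscle, 12 endothelial, 9 erythroid, 11 podocyte and 30 ribosomal protein genes fell. In the same way 20 leukocyte, 13 complement, 14 interferon, 23 NF-kB, 13 immediate early, 17 proximal tubule and 20 respiratory chain genes rose. The limma fit called 8393 of 13114 probes, 4161 higher and 4232 lower in adults. With slide as a block the count was 715 (298 higher, 417 lower). With arrays scaled to 1 median, which put the median of all probes at -0.57, it was 9165 (1582 higher, 7583 lower).

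**Figure D5:**
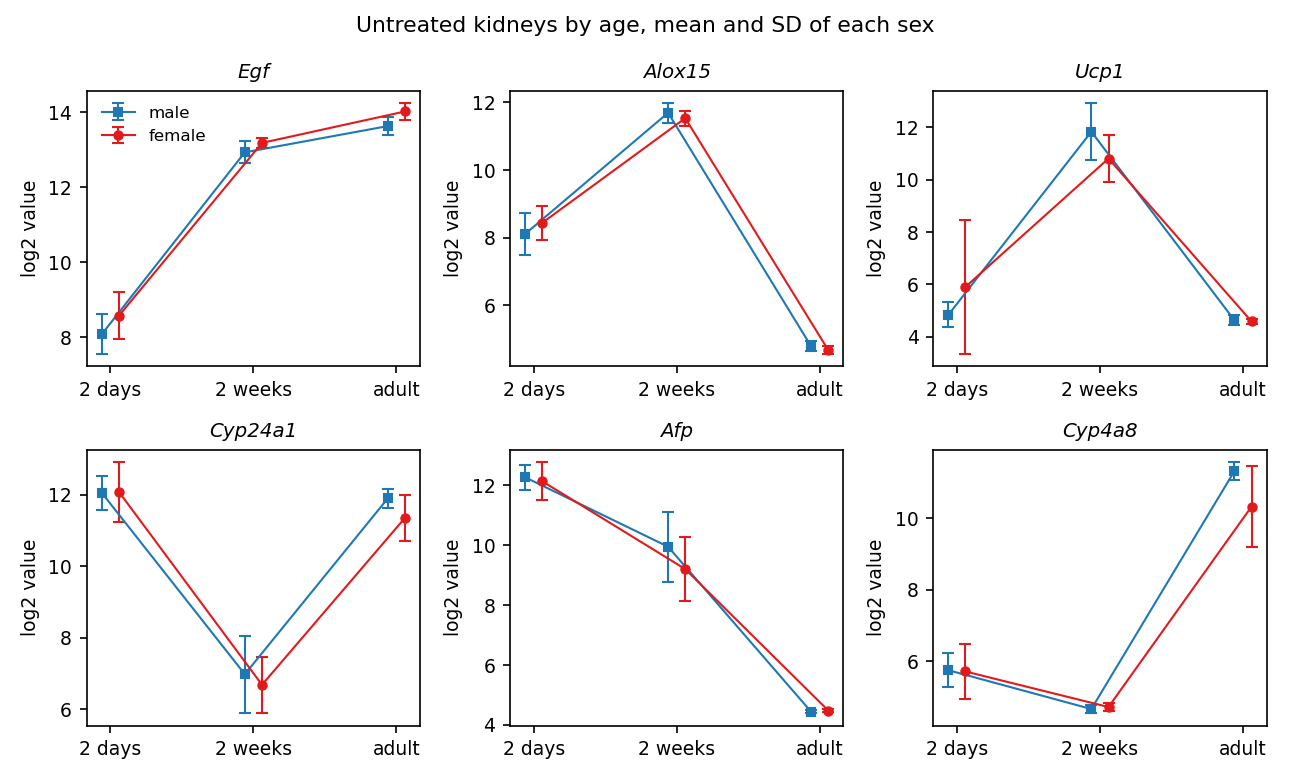
Mean log2 value ± SD in untreated males and females (points and bars) at 2 days, 2 weeks and adulthood (horizontal axis) for Egf, Alox15, Ucp1, Cyp24a1, Afp and Cyp4a8. In males Egf went from 8.09 to 12.93 and 13.63, Alox15 from 8.11 to 11.69 and 4.79, and Cyp24a1 from 12.05 to 6.98 and 11.90.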

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

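The exact permutations of list means were added after camera's calls were seen. The slide test of the matrix list and the tests of untreated 2-week male 6 as an adult sample and as an older kidney were chosen after the result was seen, and the bounds for a share of adult RNA in that array were set before its own value but after its place between the ages was known; the scaling of list medians and their values without that array were computed afterwards too.

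Higher matrix genes in 2-day PDTC pups were the list with the smallest camera p at that age. An exact permutation of treatment within sex but not slide gave p = 0.00252 for the list mean (0.21 higher, 0.0325 adjusted over 31 lists). This argues against chance among these pups as far as they are independent. The median of 0.17 was 0.133 with slide as a block and 0.14 without slide 6, which held no PDTC pups of that age. The mean difference was 0.165 adjusted for the share of probes above background. None removed most of it, but without intervals or a joint fit slides and signal stay open. With an estimated correlation the list was not called (adjusted p = 0.308). Litters are not given in the sources used here: a litter effect stays open, as does an effect of PDTC, a hypothesis here.

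In adults the PDTC differences of the injury and leukocyte lists had opposite signs in the sexes. The sex difference of the effect on the mean of the injury list was 0.61 (exact permutation p = 0.0567), and that of leukocytes 0.80 (p = 0.0433), matrix 0.49 (0.0522), cell cycle 0.48 (0.0467) and interferon 0.56 (0.167). With slide as a block the injury difference was 0.679, and leaving out 1 rat it ranged from 0.444 (without PDTC female 5) to 0.758 (without PDTC male 2), which argues against slides or a single rat as the whole cause. Chance among the rats is a candidate explanation that the injury test leaves open, and the 5 tests were not adjusted for their number. Injury means were 10.52 in untreated females against 11.06 in untreated males, and 10.92 against 10.85 with PDTC. An effect of early PDTC that differs by sex stays open. So does a difference in the stage of kidney damage at 36 and 42 weeks, which was not tested.

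Untreated 2-week male 6 stood apart from the other 5 males of its group. On an axis from the 2-week mean (0) to the adult mean (1) of the other untreated males it lay at 0.408, against -0.0066 to 0.080 for the others and 0.760 for the lowest adult, which argues against an adult sample under a 2-week label. A share of adult RNA would raise adult genes, but the probes at least 4-fold higher in adults showed a median of 0.0565 of their age change. It may reflect its slide, the only pup array on an adult slide, since its deviation correlated at 0.343 across probes with that of the slide among adults. An older kidney cannot be told apart from this: the probes at least 4-fold lower in adults showed 0.264 of their change while the higher ones hardly moved, and no other pup shares the slide.

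Single arrays lay far from the rest of their group for 50 of 717 groups of values, where chance marks about 1 in 20 groups, or 35.85. The log2 value of each is given with, in brackets, its gap to the nearest array as a share of the range of its group. At 2 days, PDTC female 2 had Msmo1 at 9.55, low (0.916) and Serhl2 at 8.07, low (0.913). PDTC female 3 had Icam1 at 8.99, high (0.871) and a mean of the matrix list of 10.37, high (0.847). PDTC male 1 had Cyp4b1 at 7.92, high (0.910). PDTC male 2 had Il1b at 5.32, low (0.892). Untreated female 1 had Aqp1 at 11.73, high (0.783), Ccl2 at 5.86, high (0.868) and Mt3 at 7.14, low (0.7103). Untreated female 2 had Gfra1 at 7.5, low (0.812), Msmo1 at 9.73, low (0.813) and Nfkb2 at 6.89, low (0.732). Untreated female 3 had Fabp4 at 10.38, high (0.890) and Ucp1 at 10.47, high (0.925). Untreated male 1 had Nox4 at 6.40, high (0.778). Untreated male 2 had Afp at 11.54, low (0.725), Slc5a2 at 9.68, low (0.752) and Ucp1 at 5.69, high (0.945). Untreated male 4 had Car15 at 6.72, low (0.770) and Slc4a4 at 10.33, high (0.749).

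At 2 weeks, PDTC female 3 had Ier2 at 8.12, high (0.851). PDTC male 4 had 11418 probes above background, low (0.914) and Nfkbia at 11.01, high (0.846). Untreated female 2 had Psmb8 at 7.70, low (0.715). Untreated female 3 had Hmgb2 at 10.74, low (0.719), Hsd11b1 at 10.25, high (0.741), Kap at 13.92, high (0.780) and Sult1c2 at 12.85, high (0.837). Untreated female 4 had C1qtnf12 at 4.82, high (0.840) but not above background. Untreated female 5 had Tef at 7.46, high (0.737). Untreated male 4 had Hnmt at 6.87, low (0.654), Slc14a2 at 10.33, low (0.661) and Thrsp at 10.10, high (0.633). Untreated male 6 had Cd74 at 10.14, high (0.752), Dbp at 7.15, high (0.741), Ptpro at 10.31, low (0.762), Sds at 5.47, high (0.866) but not above background, Sqle at 8.10, low (0.644) and Wt1 at 6.20, low (0.827).

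In adults, PDTC male 2 had Usp2 at 9.86, low (0.736). PDTC male 3 had Nfil3 at 10.27, high (0.783) and Pcgf2 at 7.39, low (0.720). PDTC male 4 had Slc22a8 at 10.01, low (0.824). Untreated female 1 had Agtr1a at 9.52, low (0.844) and Ucp1 at 4.74, high (0.739). Untreated female 2 had Spp1 at 13.69, low (0.747). Untreated female 5 had Adh6 at 9.59, low (0.822) and Dhrs7l1 at 6.0, high (0.730). Untreated male 3 had Slc12a3 at 12.31, high (0.810). Untreated male 4 had Ccl2 at 10.90, high (0.784).

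PDTC effects differed between the sexes or ages for 24 lists in camera's test of the difference itself with the preset correlation, and none with an estimated one. Median log2 differences are given, with camera's adjusted p in brackets. At 2 days (female minus male) these were proximal tubule 0.40 (1.7e-05), metal response 0.17 (0.0381) and respiratory chain 0.081 (0.0284), with adjusted p = 0.622 to 0.634 with an estimated correlation. At 2 weeks these were erythroid 0.19 (0.00384), proximal tubule -0.17 (0.0125), injury 0.14 (9.1e-04), leukocytes 0.12 (0.0304) and NF-kB components and targets 0.11 (0.0304), with adjusted p = 0.431 to 0.656 with an estimated correlation. With arrays scaled to 1 median, those of NF-kB and injury at 2 weeks turned to -0.0042 and -0.071 (0.14 and 0.070 relative to all probes). In adults these were leukocytes 0.77 (5.8e-07), complement 0.68 (0.00701), injury 0.60 (5.1e-06), interferon 0.59 (6.4e-04), matrix 0.50 (2.2e-04), cell cycle 0.39 (1.2e-04), circadian clock -0.33 (0.0312), heat shock -0.28 (0.0312), ribosomal proteins 0.18 (0.0173) and organic ion transporters -0.17 (0.0367), with adjusted p = 0.537 to 0.767 with an estimated correlation. Between 2 weeks and 2 days (later minus earlier effect) these were adipose -0.26 (0.0239), matrix -0.18 (4.5e-08), cholesterol 0.15 (0.00898), proximal tubule 0.14 (0.0239), cell cycle 0.095 (0.00898) and immediate early genes -0.085 (0.0239), with adjusted p = 0.347 to 0.930 with an estimated correlation.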

How the results depend on the processing

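The filter on the deposited p-value with a signal above background, slide as a random block, leaving out slide 6, slide with an estimated correlation for lists, and that correlation without untreated 2-week male 6 were chosen after the data were seen; all other alternatives were planned, and all planned ones were run. In adults against 2 weeks, slide as a block could not be fitted without untreated 2-week male 6. No paired analysis was possible because the labels give no replicate numbers. Where values moved, the cause was not tested. Signal over background limits dim genes: their folds are compressed or given as bounds, and the adult arrays, with fewer probes above background, tested fewer.

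Of 21 counts of probes or lists, 14 stayed within 1.5 times with all 59 arrays in 1 fit, 15 with array weights, 18 with arrays scaled to 1 median, 19 with the deposited values, with no normexp correction and with slide as a fixed term, 20 with no filter and 20 with the filter on the deposited p-value. With slide as a random block 16 of 18 did, and without slide 6 14 of 15. An estimated correlation took the lists called for PDTC to 0 at 2 days, 0 at 2 weeks and 0 in adults, and slide with an estimated correlation did so as well (0, 0 and 0). With all 59 arrays in 1 fit PDTC called 1 probe at 2 days (0 higher, 1 lower), 51 in adults (28 and 23), 303 in adult males (187 of them higher) and 129 in adult females (75 and 54), the adult sex difference of the effect 435 (223 and 212), the adult sexes 1018 (453 and 565), and 4 lists were called in adults. Array weights gave 373 probes for PDTC at 2 days, 38 in adult males, 1 for the adult sex difference of the effect, 1 for the sexes at 2 days, 237 for the adult sexes and 4 adult lists. With arrays scaled to 1 median the adult sexes gave 42 (24 higher, 18 lower), 2 weeks against 2 days 2722 (1384 and 1338) and adults 4 lists; adults against 2 weeks gave 9165, split 1582 higher and 7583 lower against 4161 and 4232, as the median of all probes was at -0.57. With no normexp correction and with the deposited values the sexes at 2 days gave 1 probe each and adults 5 lists each, with no filter adults 5 lists, and with the filter on the deposited p-value 3. Slide as a fixed term gave 3 adult lists and 715 probes for adults against 2 weeks (298 and 417). Slide as a random block gave 1 probe in 2-day males and 1 for the sexes at 2 days, which also had 1 (1 higher, 0 lower) without slide 6.

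Leaving out single arrays gave these ranges. PDTC at 2 days had 0 to 258 probes (see above) and 4 to 6 lists, 2-day males 0 to 4 (PDTC male 4) and the 2-day sexes 0 to 1 (untreated female 2). PDTC at 2 weeks had 2 to 8 lists (see above). Adult males had 0 to 10 (PDTC male 2), the adult sex difference of the effect 0 to 2 (untreated female 4), and the adult sexes 88 to 171 (98, 94, 88 and 96 without untreated male 1, male 2, female 1 and female 4). Adult lists went from 0 (untreated male 5) to 7 (PDTC male 5 or PDTC female 2), with 2 without untreated female 2, PDTC female 1 or 3, 3 without PDTC male 1 or 3, 4 without untreated male 1, 3 or 4, PDTC male 2, PDTC female 4 or 5, 5 without untreated female 5 and 6 without untreated male 2. 2 weeks against 2 days had 4725 to 5795, adults against 2 weeks 8068 to 8761 and the age difference of the effect 0 to 1 (2-week PDTC male 4). All other comparisons had 0 to 0 in limma, with 100 to 1442 probes at an unadjusted p under 0.05.

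Of the genes that the rule named, 284 had passed and 536 had not. In adults against 2 weeks, scaling to 1 median turned Cox5b to -0.057, Atp5mg to -0.13, Slc31a1 to -0.19, Hspa9 to -0.057, Serpinh1 to -0.080 and Slc22a12 to -0.17, and Fdx1, which had not passed, to -0.49, all above the median of -0.57 of all probes; slide as a fixed term turned Rps24 to -0.24, Serpinh1 to -0.062 and Hoxa11 to -0.0088. Among the 284, scaling to 1 median ended 25 further calls, slide as a fixed term 60, no filter 4 and the filter on the deposited p-value 1, and 277 passed without each array in turn. Among the 536, 81 passed with all 59 arrays in 1 fit, 34 with array weights, 7 with no normexp correction, 6 with the deposited values, 4 with slide as a random block and 1 with slide as a fixed term. Of 113 calls of lists 15 changed sign under a scaling, and 0 of these 15 did relative to all probes. The other calls were not counted relative to all probes.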

Other observations

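In this part the exact permutations of list means were chosen after camera's calls were seen, and the reading of both correlations was changed after their values were seen; the fits, the splits and the correlations themselves were planned.

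Lists that camera did not call between ages held single genes that changed in untreated kidneys. Of 18 genes of aldehyde dehydrogenases and xenobiotic enzymes, 8 rose and 5 fell from 2 days to 2 weeks (median 0.0075; camera adjusted p = 0.197). Fmo1, a flavin monooxygenase, rose by 2.08 ± 0.11 and Aldh18a1, of proline synthesis, fell by 0.55. From 2 weeks to adulthood 9 of 18 rose and 4 fell, with a median of 0.30 (-0.29 with arrays scaled to 1 median, 0.29 relative to all probes; camera adjusted p = 0.297). Cyp1a1, induced by aryl hydrocarbons, was at least 7.85-fold higher in adults, and Cyp1b1 fell by 2.92 and Aldh1a2, which makes retinoic acid, by 2.45. Of the circadian clock genes 5 of 15 rose and 2 fell by 2 weeks (median 0.097; camera adjusted p = 0.206). Per2 rose by 0.60 and Cry1 fell by 0.40. By adulthood 5 of 13 rose and 3 fell (median 0.42; -0.28 with arrays scaled to 1 median, 0.29 relative to all probes; camera adjusted p = 0.297). Nr1d1, a repressor of the clock, rose by 3.09 ± 0.12, Tef by 1.03 and Dbp by 1.96 (0.47 with slide as a block, limma adjusted p = 0.666), while Bmal1 was at least 1.39-fold lower. The time of day of collection is not given in the sources used here. Of the heat shock genes 4 of 14 rose and 1 fell by 2 weeks (median 0.075; camera adjusted p = 0.0856), Cryab by 1.52, and 7 of 14 rose and 3 fell by adulthood (median 0.15; -0.51 scaled to 1 median, 0.064 relative to all probes; camera adjusted p = 0.25), Bag3, a co-chaperone, by 1.07.

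Further lists that camera did not call held single genes that rose and single genes that fell after 2 weeks, where 8393 of 13114 probes were called in all. Of 18 genes of the loop of Henle and distal tubule 8 rose and 2 fell by adulthood (median 0.29; -0.27 with arrays scaled to 1 median, 0.30 relative to all probes), with the thiazide-sensitive cotransporter Slc12a3 at 1.64 ± 0.13. Of 25 collecting duct genes 14 rose and 6 fell (median 0.47; -0.27 and 0.30 likewise), among them the water channel Aqp4, which fell by 2.12, to above background on 1 of 10 adult arrays. Of 14 renin-angiotensin-aldosterone genes 6 rose and 5 fell: Hsd11b1, which regenerates active glucocorticoid, rose by 3.12 ± 0.13 and Agtr1a, an angiotensin receptor that had risen by 2 weeks, fell by 1.38. Of 16 nephron progenitor genes 7 fell and 2 rose (median -0.32), with Wnt4, an inducer of nephrons, at least 6.13-fold lower. Injury and repair genes rose in 9 of 20 cases and fell in 6 (median 0.27; -0.51 and 0.062 likewise), Igfbp1 by 3.02 and Tnfrsf12a, a receptor of the TNF family, by 2.36. Of 18 adipose genes 9 fell and 5 rose (median -0.28), Fabp4 by 2.94 in the first direction, and of adrenal genes 2 of 9 rose and 1 fell. The camera test called none of these 7 lists (adjusted p = 0.101 to 0.712). Among PDTC rats 9 of 10 adrenal genes were lower at 2 days (median -0.10; exact permutation p = 0.106, adjusted 0.348) and 9 of 10 at 2 weeks (median -0.11; p = 0.0528, adjusted 0.471), and 17 of 19 adipose genes were lower at 2 weeks (median -0.11; p = 0.421, adjusted 0.917; list mean lower in 7 of 10 rats). Adult fatty acid oxidation genes, with a median of -0.082 (0.032 with arrays scaled to 1 median, -0.023 relative to all probes), had the smallest exact p of the adult lists, 0.0308 (adjusted over 31 lists, 0.769).

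Each comparison was set against 100 splits of the same arrays into groups of the same sizes, the real one included. Counting called probes, few splits gave as many in the comparisons with calls. For the adult sexes 2 of 100 did (157 against up to 214). Another split thus called more than the real one, and it lay less evenly over slides (0.8 against 0.2). Chance was unlikely there but not excluded. For 2 weeks against 2 days (5059 against up to 1738) and adults against 2 weeks (8393 against up to 4481) 1 of 100 did, which argues against chance among the arrays. For the other comparisons 0 probes passed in limma, so probes at an unadjusted p under 0.05 were counted, and chance could not be excluded. The splits that gave as many, of 100, with the real and highest other counts, were 5 (2085 against up to 2769) at 2 days, 36 (697 against up to 3106) at 2 weeks and 23 (668 against up to 2309) in adults for PDTC in both sexes. By sex they were 11 (1476 against up to 2774) in males and 26 (968 against up to 2110) in females at 2 days, 92 (432 against up to 2558) and 24 (422 against up to 1936) at 2 weeks, and 13 (945 against up to 3087) and 31 (681 against up to 1604) in adults. For the sex difference of the PDTC effect they were 76 (309 against up to 3091), 82 (186 against up to 1965) and 25 (919 against up to 3676) at the 3 ages, for untreated sexes 81 (224 against up to 3089) at 2 days and 94 (368 against up to 2550) at 2 weeks, and for the age difference of the effect 48 (473 against up to 5017). For gene lists they were 36 (5 against up to 11), 21 (5 against up to 9) and 92 (1 against up to 13) at the 3 ages, 67 (4 against up to 13) in adult males, 28 (8 against up to 14) in adult females, 14 (10 against up to 12) for the adult sex difference of the effect and 6 (9 against up to 10) for the untreated adult sexes, and chance could not be excluded for any of these counts.

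Some splits gave several times the real count, which points to a structure of the samples. On a scale where 0 is an even spread over slides and 1 means no slide in common, the highest split lay at 0.818 against 0.255 for the real one at 2 weeks in both sexes, at 1.0 against 0.5 in 2-week males, 0.833 against 0.167 in 2-week females, 1.0 against 0.6 in 2-day females, 0.8 against 0.4 and 0.833 against 0.333 between untreated sexes at 2 days and 2 weeks, and 0.8 against 0.2 between adult sexes. In adults against 2 weeks the real grouping was the less even one (0.627 against 0.909): there the splits bear on chance among arrays, not on slides, and slide as a block took the count from 8393 to 715. The highest splits of 2-day females and of 2-week males thus followed slides fully. With slide as a block the real counts at an unadjusted p under 0.05 were 822 and 653 there, and 1559 and 1170 in both sexes at 2 days and 2 weeks, and limma called 122 probes between the adult sexes. In adults the highest splits for PDTC lay at 0.3 against 0.2 in both sexes, 0.4 against 0.2 in males and 0.4 against 0.2 in females, so none followed slides fully. Nor did those of the sex difference of the effect at 2 days (0.444 against 0.333, with a median split of 0.444), 2 weeks (0.667 against 0.25, 0.472) and in adults (0.4 against 0.2, 0.3) or of its age difference (0.337 against 0.184, 0.332); the source of this structure was not tested.

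A first hypothesis was that PDTC pups at 2 days differ from untreated pups in the direction of maturation. Across 9643 genes, which are not independent replicates, the PDTC effect and the change from 2 days to 2 weeks, with the untreated pups split between both, correlated at 0.0880, and 43 of 100 permutations of treatment within sex, the real one included, gave as large a value (range -0.231 to 0.194). A second was that the sexes share an effect at 2 days. The effects in males and in females correlated at 0.507 across the same genes, and 8 of 100 permutations gave as much (range -0.665 to 0.650). Both had been set to count as excluded unless the correlation exceeded that of 95 of 100 permutations. That was wrong, because missing this mark does not exclude an effect. Whether either hypothesis holds cannot be told apart from chance with 18 pups, since permuted labels reached values of the same size.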
